A study of Nicotiana tabacum with 7 samples.

How the data were processed

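The samples were Nicotiana tabacum plants of the cultivar Honghua Dajinyuan. PEG6000, a polyethylene glycol, is a polymer that roots do not take up readily and that lowers the water available to them. Tag-based digital gene expression (DGE) was measured in roots at 0 h and after 6 h and 48 h in 20% PEG6000. Small RNA was sequenced from control roots, control stems, control leaves and a pool of equal amounts of RNA from the roots treated for 6 h and 48 h. Each of the 7 groups held 1 library, and there was no replicate in any group. No untreated root library at 6 h or 48 h is among the groups, so time and treatment were changed together.

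The deposited DGE tables list, for each gene model, a count and a TPM value, then each tag with its own copy number and TPM, per the file headers. A tag is a 21-base piece of a transcript that starts at a cutting site. Per the labels' protocols, each library held both DpnII and NlaIII digests. All tags in the tables began with CATG, the NlaIII site, so the counts used here rest on that enzyme alone. In all 3 tables each deposited count equalled the sum of the copies of its tags, no tag was listed for more than 1 gene model, and the lowest copy number was 2. A gene model that a table did not list was taken as 0 counts. The deposited TPM values were scaled by the authors to library totals of 3394400, 3384000 and 3333100 tags at 0 h, 6 h and 48 h, as worked out from the ratio of count to TPM. The counts on gene models came to 773301, 740058 and 760516, which were 22.8%, 21.9% and 22.8% of those totals. The mapper, its settings and the build and organism of the gene models are not given in the sources used here. Of the 21128 gene models listed, 20959 had identifiers starting with NbS and 169 with NbC, and 20240 carried a description. Gene names are those descriptions. None of the identifiers matched the reference gene table of the tobacco assembly ASM71507v2 (0 matches), so no coordinates are given. A description names the closest protein found by the authors and can be the same for several gene models. Tags that near-identical gene copies share could have been given to one copy or dropped, so values of members of multigene families are uncertain in that respect.

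The deposited small RNA files give a read count for each distinct sequence of 18 to 44 nt, per the file headers. Trimming and quality filters are not given in the sources used here, and the sequences carried no annotation or mapping. The libraries held 17158429 reads for control root, 16979529 for drought root, 19078674 for control stem and 14061196 for control leaf. RPM values are reads scaled to these totals.

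CPM values are counts scaled to the summed counts on gene models. A gene was tested where 1 of the 2 libraries compared held at least 10 counts. The test was an exact two-sided binomial test of the counts of the 2 libraries given their totals, with Benjamini-Hochberg adjustment over the genes tested. A gene was called where the adjusted p was below 0.001 and the CPM differed at least 2-fold. The quasi-likelihood test of edgeR could not be fitted because no group had a replicate. The binomial test compares 2 libraries, not 2 conditions. Intervals are exact 95% intervals and cover counting error only, since tags and reads amplified by PCR are not independent molecules. Where a gene had 0 counts in 1 library, its fold was computed against a floor of 3 counts in that library and is given as "at least". The lower bound of the interval lies below that fold, because at 0 counts the interval allows for more than the floor. For the terpene synthase at 6 h it was 30.6 against 38.3. "At least" is therefore relative to the floor and is not a smallest fold. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; plots used matplotlib 3.10.9. Alternatives used edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3.

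Gene groups were 49 lists of words matched to the descriptions, written before the data were examined. They covered water stress, hormones, nicotine and polyamine synthesis, oxidative stress, cell wall, defence, transport, ribosomes, cell cycle, 18 families of transcription factors and markers of shoot tissue and of microbes. For each list with at least 3 measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. Its percentile is a description of these libraries and not a test across samples. The list of circadian clock genes and the list of suberin and Casparian strip genes were added after the results were seen.

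The genes named follow a rule written before the data were examined. From each comparison it takes the 6 higher and 6 lower called genes with an informative description whose fold was largest by the interval bound nearest to 1. From each list it takes the called member with the highest mean CPM and the called member with the largest fold by the same bound. Not every gene taken by the rule is printed. At 6 h ornithine decarboxylase, putrescine N-methyltransferase, osmotin and the PR10 gene NbS00012812g0001.1 were named outside the rule, after their values were seen.

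Reads of 20 to 22 nt were given to 28 small RNA families, fixed beforehand as 33 textbook sequences, where they had at most 2 mismatches at an offset of at most 1 base. Families with at least 10 reads in 1 library were tested as the genes were. Naming a read by such a match does not show that it comes from a microRNA gene of tobacco. Length shares were computed over reads of 18 to 30 nt with exact binomial intervals.

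The calculations were tested on simulated data. With counts drawn from the library means for 9869 genes at 6 h against 0 h, the test called 71 of 100 genes changed 3-fold, 85 of 100 genes changed 6-fold and 0 unchanged genes. At 48 h against 0 h (9967 genes) it called 75 and 94 of 100, and at 48 h against 6 h (9823 genes) 73 and 90 of 100, again with 0 false calls. The simulated counts varied by counting error alone, so 0 false calls does not measure false calls from variation between plants or libraries. Recovery was not split by count level, so these shares may not hold for genes with few counts. Of 100 unchanged lists drawn for 6 h against 0 h, 1 lay outside the central 95%. Simulated family reads with up to 2 mismatches were all given to their own family (660 of 660 at each number of mismatches), and 0 of 100000 random sequences were given to any.

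Alternatives were another scaling (TMM factors of edgeR, size factors of DESeq2, totals without the 10 most abundant genes, the authors' library totals), no filter or a filter of 50 counts, a fold threshold of 4, edgeR's exact test with an assumed biological coefficient of variation of 0.2 or 0.4, and only the tag listed as number 1 of each gene. For small RNA they were other scalings, no mismatch, a minimum of 100 reads, distinct sequences, and leaving out the 100 most abundant sequences.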

Results

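Transcript tags were counted in tobacco roots before treatment and after 6 h and 48 h in 20% PEG6000, which lowers the water available to the root. Small RNA was sequenced from control roots, from a pool of roots treated for 6 h and 48 h (drought roots), and from control stems and leaves. Each group held 1 library. The root transcript libraries at 0 h, 6 h and 48 h held 3394400, 3384000 and 3333100 tags by the authors' totals, of which 773301, 740058 and 760516 were counted on gene models. The tables listed 17087, 16155 and 17503 gene models, and 13101 of 21128 were listed at all 3 times. The small RNA libraries held 17158429 reads for control root, 16979529 for drought root, 19078674 for stem and 14061196 for leaf. No group had a replicate, so the exact binomial test compares libraries and not conditions, and all intervals cover counting error only. Genes called had an adjusted p below 0.001 and a fold of at least 2. No untreated root was sampled at 6 h or 48 h, so a change with treatment cannot be separated here from a change with time.

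The comparison of 6 h with 0 h asked which transcripts had moved in the early hours in PEG6000. Of 9946 genes tested, 335 rose and 426 fell (7.65% called), and 3456 had an unadjusted p below 0.05. With an assumed biological coefficient of variation of 0.4, only 1 of the genes higher at 6 h than at 0 h and 2 of the genes lower at 6 h than at 0 h passed. Which direction led depended on scaling: TMM gave 382 higher and 363 lower, and the authors' totals gave 298 and 491. Genes of nicotine synthesis rose at 6 h, with 5 of 7 measured members higher, none lower and a median log2 ratio of 2.17, above every one of 10000 matched random lists (percentile 100). L-aspartate oxidase, which opens the route to the pyridine ring of nicotine, rose 8.97-fold (4.92 to 17.9). The A622 gene, needed late in nicotine synthesis, rose 3.63-fold (3.15 to 4.20). Ornithine decarboxylase NbS00041791g0004.1 rose by a log2 ratio of 2.51 (2.13 to 2.91) and putrescine N-methyltransferase NbC25359043g0001.1 by 2.34 (1.04 to 3.90); together they make the methylated putrescine of the pyrrolidine ring.

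Pathogenesis-related proteins held the largest number of higher members at 6 h, with 15 of 33 measured higher and none lower (median log2 1.02, percentile 100). Endochitinase A, which cuts fungal chitin, rose 2.54-fold (2.37 to 2.71) to 3115 counts. The minor form of pathogenesis-related protein R, of the thaumatin family, went from 0 to 43 counts, at least 15.0-fold. Osmotin NbS00026613g0001.1, an antifungal protein first found in salt-adapted tobacco cells, rose by a log2 ratio of 1.5 (1.35 to 1.66). In the PR10 gene NbS00012812g0001.1 the log2 ratio was 2.5 (2.26 to 2.74). A proteinase inhibitor of type 2, which blocks the digestive proteases of insects, rose 6.05-fold (4.70 to 7.88), the only called member of the 5 proteinase inhibitors. The photosynthesis list, a marker of shoot tissue, had a median log2 ratio of -0.94 between the same libraries (percentile 0.755). Its single higher member of 13 was the alpha subunit of the RuBisCO large subunit-binding protein, a plastid chaperonin, at 2.16-fold (1.66 to 2.83).

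The largest increases at 6 h among described genes, ranked by the lower bound of the interval, were in a terpene synthase (0 to 110 counts, at least 38.3-fold against the floor of 3 counts, interval bound 30.6) and a RING1-like ubiquitin ligase (0 to 75 counts, at least 26.1-fold). A tetrahydroxychalcone 2'-glucosyltransferase, which attaches glucose to a flavonoid precursor, rose at least 20.6-fold. GIGANTEA, a part of the circadian clock that also acts on flowering, rose 21-fold (13.4 to 34.8; adjusted p 2.06e-94, exact binomial test); the hours of sampling are not given in the sources used here. A glucan endo-1,3-beta-glucosidase rose at least 16.7-fold and ethylene-responsive-element-binding factor 13 rose 33.4-fold (12.7 to 125). The F-box protein PP2-A13 fell 124-fold (34 to 1029), from 259 counts to 2. CONSTANS, which reads day length for flowering, fell from 114 counts to 0 (at least 36.4-fold). An At5g37260-like gene of the clock's MYB family fell from 36 to 0 counts, at least 11.5-fold. A cytochrome P450 82C4-like gene fell at least 16.9-fold, an AP2/ERF gene at least 11.8-fold, and lumazine synthase, an enzyme of riboflavin synthesis, 23.7-fold (8.96 to 88.6). The terpene synthase, the glucan endo-1,3-beta-glucosidase, the At5g37260-like gene and lumazine synthase each rested on 1 distinct tag.

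At 6 h the most abundant dehydrin, of a family that protects membranes and proteins in drying cells, fell 5.81-fold (4.18 to 8.26), and the other 2 of 3 measured late embryogenesis abundant (LEA) members did not pass (list median -0.27). In abscisic acid synthesis and signalling, 2 of 35 members rose and 3 fell (4 when adjusted over the list alone; median -0.40). Among the lower ones were the phosphatases 2C 49-like, 4.14-fold (3.08 to 5.63), and NbS00016615g0012.1, 5.90-fold (3.57 to 10.3). Clade A of the phosphatases 2C blocks abscisic acid signalling, but neither description gives a clade. Their place in this list rests on the word match alone. None of 13 measured genes of osmolyte synthesis and none of 12 of sucrose and starch metabolism was called, and the proline degradation list had 1 measured member, which did not pass. Of 15 aquaporins only PIP2;1, a water channel of the plasma membrane, was called, at 2.30-fold higher (1.68 to 3.17).

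Polyamine synthesis fell in part at 6 h, with 4 of 15 measured members lower and 1 higher. S-adenosylmethionine decarboxylase 2, which supplies the aminopropyl group of spermidine, fell 4.07-fold (3.70 to 4.48), from 2282 to 537 counts. A second model of that enzyme fell 6.60-fold (4.11 to 11.1). Antioxidant enzymes shifted up (2 of 22 higher, 1 lower; median log2 0.83, percentile 100), with iron superoxide dismutase 2.11-fold higher (1.69 to 2.64). Glutathione S-transferases, which couple glutathione to toxic compounds, had 4 of 12 members higher and none lower (percentile 98.6), led by NbS00059105g0003.1 at 3.48-fold (3 to 4.06). Heat shock proteins and other chaperones had 9 of 69 higher (11 adjusted over the list alone) and none lower (percentile 99.9); heat shock protein 90 rose 3.04-fold (2.53 to 3.66) and NbS00010856g0013.1 rose 9.83-fold (5.95 to 17.3). Lipid transfer proteins had 3 of 10 higher (percentile 99.8), with NbS00046944g0001.1 at 2.92-fold (2.65 to 3.23).

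Hormone and wall genes moved in both directions at 6 h. In ethylene synthesis and signalling 4 of 21 rose and 2 fell, and 1-aminocyclopropane-1-carboxylate oxidase 3, which makes ethylene, rose 2.52-fold (2.15 to 2.96). In jasmonate synthesis and signalling 1 of 16 rose, a lipoxygenase at 3.85-fold (3.05 to 4.90), and 2 fell, among them the repressor JAZ3 at 16.7-fold (7.44 to 46.7). JAZ3 rested on 1 distinct tag. Auxin genes gave 2 of 54 higher and 3 lower, cytokinin genes 1 of 16 lower (an ARR12-like response regulator, 3.86-fold) and gibberellin genes 0 of 11 called. Cell wall genes gave 4 of 85 higher and 11 lower (5 and 12 adjusted over the list alone): an extensin-like structural protein rose 2.67-fold (2.55 to 2.80) to 6136 counts, and an expansin-like gene, of a family that loosens walls, fell 6.55-fold (5.37 to 8.06). Class III peroxidases gave 2 of 39 each way (3 lower adjusted over the list alone), with peroxidase 4 higher at 2.07-fold (1.88 to 2.27) and a cationic peroxidase lower at 2.78-fold (2.5 to 3.10). Phenylpropanoid genes gave 3 of 31 higher (4 adjusted over the list alone) and 1 lower.

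Among transcription factors at 6 h, AP2/ERF genes fell most often, with 15 of 40 lower and 3 higher (median log2 -0.95, percentile 0). DREB4 NbS00007425g0002.1, of a subfamily that acts on water stress genes, fell 2.12-fold (1.81 to 2.5). Basic helix-loop-helix genes had 5 of 29 lower and none higher, with a bHLH25-like gene at 6.79-fold (3.49 to 14.8), and Dof genes had 1 of 9 lower with a median of -1.67 (percentile 0.02). Heat stress factors had 3 of 8 higher; the B-3-like model NbS00009619g0006.1 rose 23-fold (7.53 to 114) from 3 to 66 counts. WRKY genes, many of them in defence, gave 2 of 33 higher and 3 lower, from 5.45-fold higher (3.62 to 8.48) to 5.04-fold lower (3.55 to 7.33). MYB genes gave 1 of 22 higher and 2 lower (3 adjusted over the list alone), TCP genes 1 of 7 each way (2 higher adjusted over the list alone) and zinc finger genes 3 of 86 higher and 4 lower. GRAS genes gave 1 of 16 lower, the growth repressor DELLA protein GAI at 2.5-fold (1.88 to 3.34), homeobox genes 1 of 20 lower and LBD genes 1 of 5 higher, an LBD41-like gene at 3.71-fold (2.67 to 5.25). No member was called among 10 NAC, 10 bZIP, 14 auxin response factor, 8 GATA, 6 MADS, 6 NF-Y and 5 SBP genes measured, although SBP genes had a median of -1.81 (percentile 0.515).

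In the remaining lists at 6 h, of 86 cytosolic ribosomal proteins 1 rose and 2 fell. Of 32 genes matched by the reference gene words 3 fell, including an alpha-tubulin at 2.87-fold (1.71 to 5.03). In the ubiquitin and proteasome list 1 of 196 rose and 17 fell. Histone and cell cycle genes gave 1 of 39 higher. The list of fermentation words gave 1 of 20 higher, a short chain alcohol dehydrogenase at 4.82-fold (3.69 to 6.37). Its role in fermentation rests on the word match alone. Nutrient transport gave 1 of 34 each way (percentile 0.735). A potassium channel was higher at 2.32-fold (1.62 to 3.38) and a nitrate transporter lower at 4.47-fold (2.53 to 8.40). No member was called in 9 microbe and virus markers or in 7 transposable elements. Of 48 lists summarised, 6 had medians above and 6 below the central 95% of random lists, where 2.4 in all would lie outside by chance.

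**Figure D1:**
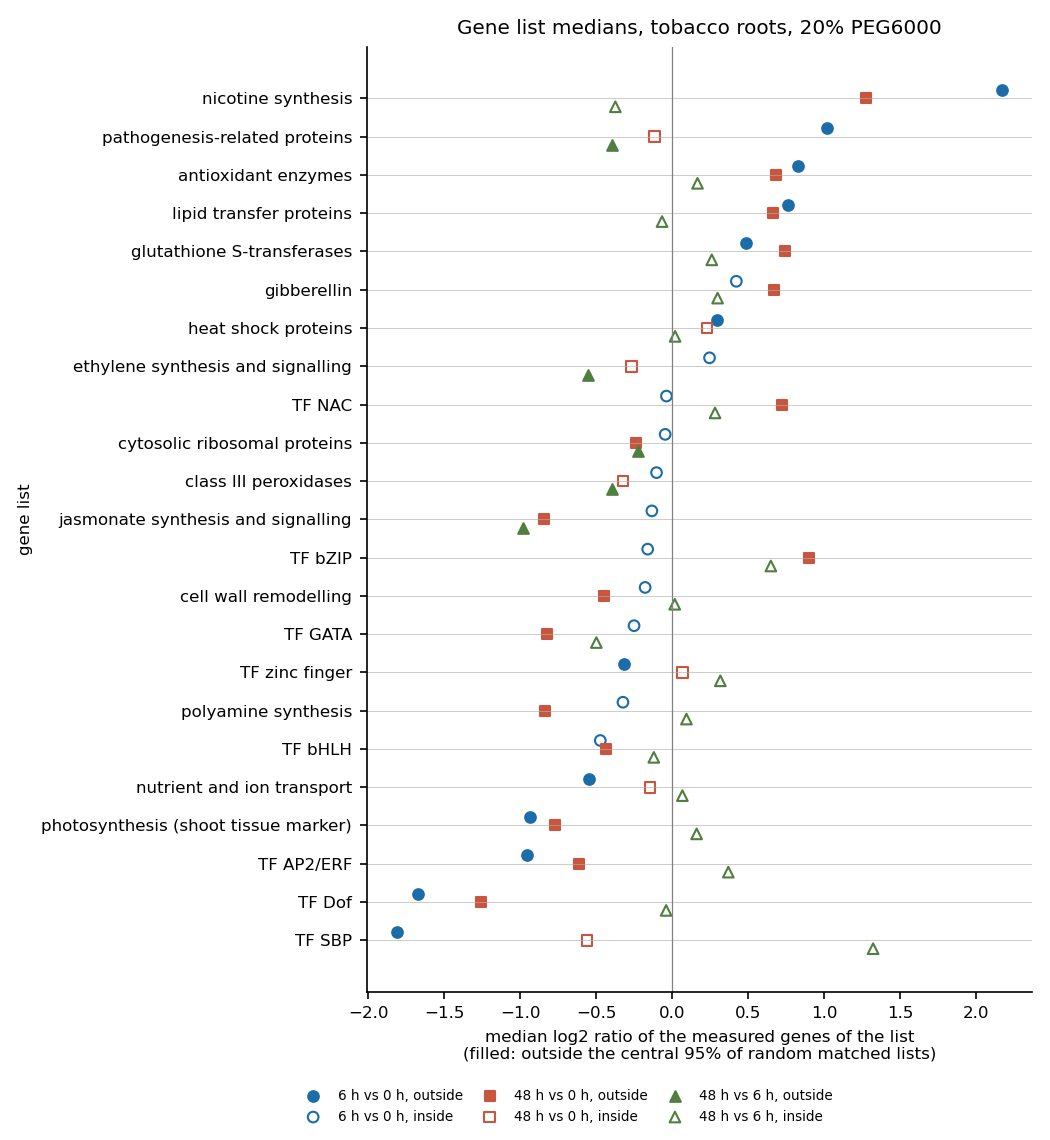
Median log2 ratio of the measured members of each gene list (horizontal axis) in root libraries at 6 h against 0 h, 48 h against 0 h and 48 h against 6 h, for lists outside the central 95% of random lists in any comparison, with filled symbols where the list lay outside. Nicotine synthesis lay at 2.17, 1.28 and -0.37, and pathogenesis-related proteins at 1.02, -0.12 and -0.40.

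The comparison of 48 h with 0 h asked what had moved after 2 days in PEG6000. More genes were called than at 6 h: of 10588 tested, 561 rose and 718 fell (12.1%), and 4454 had an unadjusted p below 0.05. With the assumed coefficient of variation of 0.4, only 4 of the genes higher at 48 h than at 0 h and 1 of the genes lower at 48 h than at 0 h passed. Nicotine synthesis stayed up with 3 of 9 members higher and none lower (median 1.28, percentile 99.7), including A622 at 2.45-fold (2.11 to 2.85) and L-aspartate oxidase at 8.39-fold (4.59 to 16.8). Antioxidant enzymes had 4 of 25 higher and 1 lower (percentile 99.7): phospholipid hydroperoxide glutathione peroxidase, which reduces lipid peroxides, rose 2.49-fold (2.29 to 2.72) to 1814 counts, and catalase 1 fell from 16 counts to 0 (at least 5.25-fold). Glutathione S-transferases split 4 higher and 2 lower of 12, with NbS00059105g0003.1 at 3.29-fold higher (2.83 to 3.84) and transferase 23 at 5.94-fold lower (3.90 to 9.37). The lipid transfer protein NbS00046944g0001.1 rose 6.24-fold (5.70 to 6.85) to 3328 counts, in a list with 3 of 10 members higher and 1 lower (percentile 97.8).

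The largest increases at 48 h were in a receptor-like kinase, 108-fold (36.7 to 527; 3 to 319 counts), and a protein phosphatase 2C with 0 and 98 counts (at least 33.2-fold). GIGANTEA rose 37.6-fold (24.2 to 62.0). A CASP-like gene rose from 0 to 86 counts, at least 29.1-fold. It is named for proteins of the Casparian strip of the root endodermis, and that name alone does not show a role there. The RING1-like ligase rose at least 23.7-fold and a quinone reductase at least 21.4-fold. CONSTANS fell at least 37.4-fold, PP2-A13 fell 42.5-fold (19.2 to 117) and an LHY-like gene, of the morning loop of the clock, fell from 61 counts to 0 (at least 20.0-fold). A vacuolar iron transporter homolog fell 20.0-fold (14.4 to 28.7; 754 to 37 counts), a wound-responsive AP2 gene 27.8-fold (13.3 to 70.1) and a glycine-rich protein at least 16.7-fold.

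Lower calls outnumbered higher ones over all genes at 48 h, and did so in several lists. Cell wall genes had 6 of 89 higher and 13 lower (7 and 14 adjusted over the list alone; median -0.45, percentile 0.01), with an endo-xyloglucan transferase, which re-joins wall polymers, 9.06-fold higher (5.88 to 14.6) and the expansin-like gene 3.54-fold lower (3.04 to 4.14). Class III peroxidases had 2 of 39 higher and 9 lower, the cationic peroxidase at 5.02-fold (4.39 to 5.76). Cytosolic ribosomal proteins had 1 of 85 higher and 10 lower (percentile 2.06), among them an S4-like protein at 3.21-fold (2.85 to 3.63) and L39 at 6.08-fold (4.30 to 8.81). Histone and cell cycle genes had 4 of 42 lower and none higher; cyclin-B1-2, which drives entry into mitosis, fell 6.59-fold (3.37 to 14.4). Polyamine synthesis split 3 to 3 of 14 (percentile 0.60), and S-adenosylmethionine decarboxylase 2 was 4.58-fold lower (4.15 to 5.06). The photosynthesis list had 3 of 13 lower and none higher (median -0.77, percentile 1.45), including a chlorophyll a/b binding protein at 15.2-fold (3.88 to 131), and a median above 0 under a filter of 50 counts.

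Water and stress genes were called in both directions at 48 h. The dehydrin was 3.44-fold lower (2.64 to 4.52), the only call among 4 LEA members, whose median was 0.42. In abscisic acid genes 3 of 39 rose and 4 fell, in osmolyte synthesis 1 of 14 fell, trehalose-phosphate synthase 6 at 2.65-fold (1.76 to 4.08), and in aquaporins 1 of 15 fell, 6.23-fold (3.06 to 14.3). Pathogenesis-related proteins had 4 of 34 higher and none lower with a median of -0.12, where osmotin was 2.29-fold higher (2.05 to 2.55) and a PR10 gene 2.75-fold (2.18 to 3.49). Heat shock proteins had 8 of 66 higher and 3 lower (4 lower adjusted over the list alone): a class I small heat shock protein rose 7.22-fold (4.45 to 12.4) and a heat shock cognate 70 kDa protein fell 2.22-fold (1.90 to 2.59). The type 2 proteinase inhibitor was 2.60-fold higher (1.97 to 3.46), the only call among 5. The list of fermentation words gave 3 of 20 higher and 1 lower. Both higher members named are described as class III alcohol dehydrogenases (2.10-fold and 5.59-fold). A match by word does not show a role in fermentation. Sucrose and starch genes gave 2 of 14 higher and 1 lower, with starch synthase IV at least 6.44-fold higher.

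Hormone genes at 48 h included gibberellin genes, with 2 of 13 higher and 2 lower (4 higher adjusted over the list alone; percentile 98.5, with a median below 0 under a filter of 50 counts): gibberellin 2-beta-dioxygenase, which inactivates the hormone, rose 2.39-fold (1.92 to 2.99), and gibberellin 20 oxidase 3, which makes its precursor, fell 3.02-fold (1.95 to 4.81). Auxin genes gave 5 of 55 higher and 6 lower, with the efflux carrier PIN6 16.9-fold higher (6.95 to 53.3). Cytokinin genes gave 3 of 22 higher and 2 lower; the phosphoribohydrolase that releases active cytokinin rose 2.61-fold (2.01 to 3.42), while the APRR1-like member at 34.1-fold (9.07 to 287) is named for a clock gene. Jasmonate genes gave 3 of 14 lower and none higher (percentile 0.74), with JAZ1 at 2.72-fold (1.98 to 3.77). Ethylene genes gave 1 of 20 each way: ACC oxidase rose 3.11-fold (1.77 to 5.74) and an ethylene receptor homolog fell 6.39-fold (2.22 to 25.2). Phenylpropanoid genes gave 3 of 32 higher and 2 lower, and nutrient transport 3 of 40 lower, a sulfate transporter at 3.25-fold (2.44 to 4.39).

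Transcription factors at 48 h fell again among AP2/ERF genes (0 of 38 higher, 9 lower, 10 adjusted over the list alone; median -0.62, percentile 0), with ERF4, a repressor, at 2.32-fold (1.98 to 2.73). Basic helix-loop-helix genes gave 7 of 30 lower (8 adjusted over the list alone), bHLH1 at 5.45-fold (2.99 to 10.7), and Dof genes 2 of 9 lower (3 adjusted over the list alone). NAC genes gave 2 of 11 higher and 1 lower (percentile 98.0) and bZIP genes 0 of 13 called with a median of 0.90 (percentile 99.3). MYB genes gave 4 of 26 higher and 5 lower (6 adjusted over the list alone), WRKY genes 3 of 35 lower, zinc finger genes 3 of 92 higher and 7 lower, and GRAS genes 2 of 17 higher, the DELLA protein RGL2 at 8.47-fold (3.63 to 24.2). Heat stress factors gave 2 of 8 higher, among them factor A3, which acts below DREB genes in drought, at 10.0-fold (4.33 to 28.3). Auxin response factors gave 1 of 15 each way (0 higher adjusted over the list alone), with factor 19, an activator of lateral root genes, 7.73-fold lower (3.51 to 20.1). Single calls came from 6 NF-Y, 5 LBD (both higher) and 7 SBP genes (lower); homeobox genes gave 1 of 25 higher and 2 lower, TCP genes 2 of 7 higher and 1 lower, and GATA and MADS genes none of 8 and 6.

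In the remaining lists at 48 h, ubiquitin and proteasome genes gave 11 of 210 higher and 13 lower, and reference genes 1 of 33 higher, a transcription elongation factor 1 homolog at 2.42-fold (2.03 to 2.90), and 3 lower. The microbe and virus words matched only plant genes among the calls: a superkiller viralicidic activity 2-like helicase, which takes part in RNA decay, was 2.11-fold higher, and a protein named for a virus receptor, of the PHO1 phosphate export family, was 4.83-fold lower. The list had 2 of 10 higher and 1 lower (2 lower adjusted over the list alone). No transposable element was called among 6 measured. Medians of 7 lists lay above and 9 below the central 95% of random lists.

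The 6 h and 48 h comparisons share the 0 h library. Of 9599 genes tested in both, 125 rose at both times (299 at 6 h, 476 at 48 h) and 239 fell at both (426 and 718). Independent lists would share 14.8 and 31.9, and 100 simulations of counting error with the shared library gave 0 of each. Unchanged genes gave 0 calls in simulated data, so that value does not measure how much overlap the shared library brings. The log2 ratios had a correlation of 0.61 and a covariance of 0.644, against 0.548 and 0.120 in the simulation. An unknown part of the overlap may come from the 0 h library itself, which with 1 library cannot be split from the rest. Of the genes higher at 6 h 41.8% were higher at 48 h, and of the lower ones 56.1% were lower. The 11 models of chlorophyll-binding proteins, a marker of shoot tissue, had 84 counts at 0 h, 18 at 6 h and 20 at 48 h. They so moved with the genes that fell at both times. The 36 models of the photosynthesis list together had 505, 450 and 416 counts, a much smaller fall. Only 2 genes were called in opposite directions: the ethylene receptor homolog and NbS00024338g0007.1, described as unknown.

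**Figure D2:**
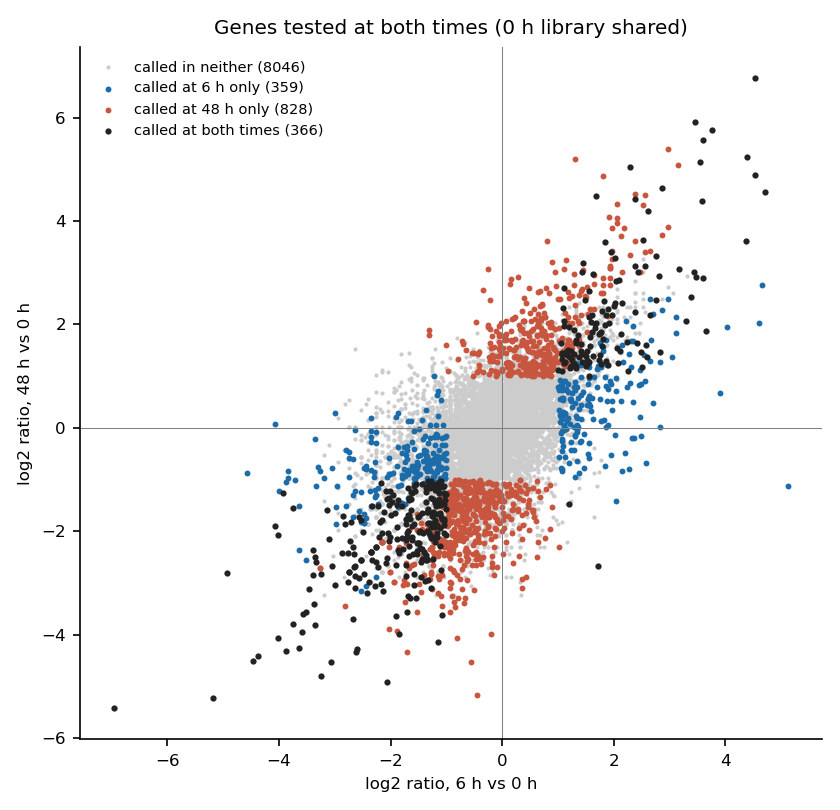
Log2 ratio at 6 h against 0 h (horizontal) and at 48 h against 0 h (vertical) for 9599 genes tested in both root comparisons, coloured by call. Of these, 366 were called at both times, 359 at 6 h only and 828 at 48 h only.

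The comparison of 48 h with 6 h asked what differed between the early and the late treated roots. Of 10172 genes tested, 418 rose and 439 fell (48.8% of calls higher), and 3887 had an unadjusted p below 0.05. The split depended on scaling: TMM gave 303 genes higher at 48 h than at 6 h and 555 genes lower at 48 h than at 6 h (35.3% higher), DESeq2 factors gave 321 and 520 (38.2%), and the authors' totals gave 496 and 383 (56.4%). The median log2 ratio of all genes was 0.13 as scaled here and -0.01 with TMM. Of the 335 genes higher at 6 h, 114 were lower at 48 h than at 6 h, and of the 426 lower genes 45 were higher. Both comparisons use the same 6 h library, so a return is expected where that library stood apart, and no value for unchanged genes was computed. Pathogenesis-related proteins were lower at 48 h than at 6 h, with 14 of 37 lower and none higher (1 higher adjusted over the list alone; percentile 0.49). Endochitinase A fell 2.69-fold (2.51 to 2.88) and PR-1A, a marker of salicylic acid signalling, went from 36 counts to 0, at least 12.3-fold. PR-1A rested on 1 distinct tag.

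Falls between 6 h and 48 h came both in genes that had risen at 6 h and in genes that had not. The terpene synthase fell at least 37.7-fold, ethylene-responsive-element-binding factor 13 fell 65.8-fold (17.8 to 549), the B-3-like heat stress factor 33.9-fold (9.02 to 286), an early nodulin gene at least 32.2-fold and the cytochrome P450 CYP71D5v3 at least 11.6-fold. Ornithine decarboxylase fell 2.52-fold (2.08 to 3.07), the only call among 9 nicotine genes. In jasmonate genes 1 of 13 rose, JAZ3 at 17.7-fold (7.86 to 49.2), and 3 fell (percentile 0.06), with the lipoxygenase at 5.53-fold (4.22 to 7.36). In ethylene genes 2 of 20 rose and 3 fell (percentile 0.19, with a median above 0 under either other count filter), with ACC oxidase 3 down 3.92-fold (3.25 to 4.74) and the receptor homolog down 21.1-fold (7.92 to 79.2). Class III peroxidases gave 1 of 38 higher and 5 lower (7 adjusted over the list alone; percentile 0.26), where peroxidase 4 fell 3.52-fold (3.13 to 3.96). The extensin-like gene fell 3.18-fold (3.03 to 3.35), among 3 of 85 wall genes higher and 6 lower. Cytosolic ribosomal proteins gave 2 of 84 higher (3 adjusted over the list alone) and 8 lower (percentile 1.28), with L39, not called at 6 h, at 6.92-fold (4.91 to 10.0).

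Genes higher at 48 h than at 6 h included an ABCG11-like transporter, of a family that exports wax and suberin lipids, from 0 to 37 counts (at least 12-fold). A protein phosphatase 2C named as a homolog of ABI2, a repressor of abscisic acid signalling, rose 3.77-fold (2.65 to 5.48), and the phosphatase NbS00003096g0006.1 6.81-fold (3.87 to 12.9). They were the 2 higher of 34 abscisic acid genes, and none fell. Arginine decarboxylase, an entry to polyamines, rose 9.24-fold (4.81 to 19.9), while the abundant S-adenosylmethionine decarboxylase proenzyme fell 2.59-fold (2.42 to 2.77); the list had 2 of 14 higher and 1 lower. Glutathione reductase rose 7.23-fold (3.27 to 18.9), and iron superoxide dismutase fell 2.52-fold (1.99 to 3.21), in a list with 2 of 25 higher and 1 lower. The lipid transfer protein NbS00046944g0001.1 rose a further 2.14-fold (2.01 to 2.27). Heat shock proteins gave 2 of 65 higher and 7 lower, aquaporins 2 of 13 lower (3 adjusted over the list alone), and AP2/ERF genes 3 of 36 higher and 1 lower, with ethylene response factor 111 at 2.70-fold (2.13 to 3.46). A NAC2 gene rose 2.49-fold (1.89 to 3.30), 1 of 2 higher among 11 NAC genes (3 adjusted over the list alone). Of 48 lists, none lay above and 5 lay below the central 95%.

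The small RNA of drought and control roots was compared to ask which families differed. Of 27 families tested 3 were higher and 4 lower in drought roots, and 23 had an adjusted p below 0.001. The most abundant change was in miR157, which targets SBP genes, at 2.03-fold (2.02 to 2.05; 18096 against 8893 RPM, reads scaled to the library total); it did not pass when scaled by TMM or by the family total. Higher by few reads were 2 families whose call was lost in most other settings, miR395, of sulfate uptake (3.33-fold, 1.61 to 7.59; 33 and 10 reads), and miR399, of phosphate uptake (2.27-fold, 1.58 to 3.32; 99 and 44 reads). Lower were miR394, which targets an F-box gene (16.4-fold, 10.5 to 26.8), miR160, which targets repressive auxin response factors (8.13-fold, 6.75 to 9.85), miR162, which targets a dicer gene (2.59-fold, 2.36 to 2.85), and miR393, of auxin receptors (2.54-fold, 1.51 to 4.44; 21 and 54 reads), whose call held in only 3 of 6 other settings. Below the fold threshold were the copper families miR398 (1.66-fold higher) and miR397 (1.54-fold), miR482 of resistance genes (1.58-fold), and the abundant miR166 (1.12-fold), miR156 (1.15-fold) and miR168 (1.00-fold).

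Genes of the target type named for these families were looked up in the transcript libraries. For miR156 and miR157, the SBP genes measured at 6 h were 5 (median log2 -1.81, none called) and at 48 h 7 (median -0.56, 1 lower). Dicer genes, of miR162, gave none of 3 at 6 h and 1 lower of 3 at 48 h. The single measured targets of miR160 and of miR394 and both of miR393 were not called at either time. For miR395 none of 7 was called at 6 h and 1 of 9 was lower at 48 h. For miR397 1 of 5 was higher at 6 h and 1 of 6 at 48 h, and for miR171 1 of 12 was higher at 48 h. For miR408 2 of 6 were higher at 6 h and 2 of 7 at 48 h, for miR164 2 of 9 were higher and 1 lower at 48 h, and for miR399 1 of 4 was higher at 48 h. For miR319, the TCP genes gave 2 higher and 1 lower of 7 at 48 h. At 48 h 1 of 4 targets of miR169 and 1 of 2 of miR827 were higher and the single one of miR166 was lower, and at 6 h the single one of miR172 was higher.

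Control organs were compared to ask how families differ between root, stem and leaf. Of 28 families 17 were called in some pair. Leaf against root gave 4 higher and 5 lower of 27: miR157 was 5.84-fold higher in leaf (5.81 to 5.87), miR171, of GRAS genes, 3.42-fold (2.97 to 3.94; call held in 3 of 6 other settings), miR160 23.7-fold lower (17 to 34.1), miR394 16.7-fold lower (10.3 to 29.0) and miR390, which starts tasiARF production, 3.69-fold lower (3.48 to 3.90). Stem against root gave 3 higher and 10 lower of 28, with miR319 of TCP genes 5.47-fold higher and miR167 of auxin response factors 8.55-fold lower (8.38 to 8.73). Leaf against stem gave 8 higher and 4 lower of 28, with miR167 19.4-fold higher (19.1 to 19.8) and miR319 23.2-fold lower (12.8 to 47.0). miR827, at 21-fold higher (5.35 to 181), rested on 31 and 2 reads, and its call held in 3 of 6 other settings.

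**Figure D3:**
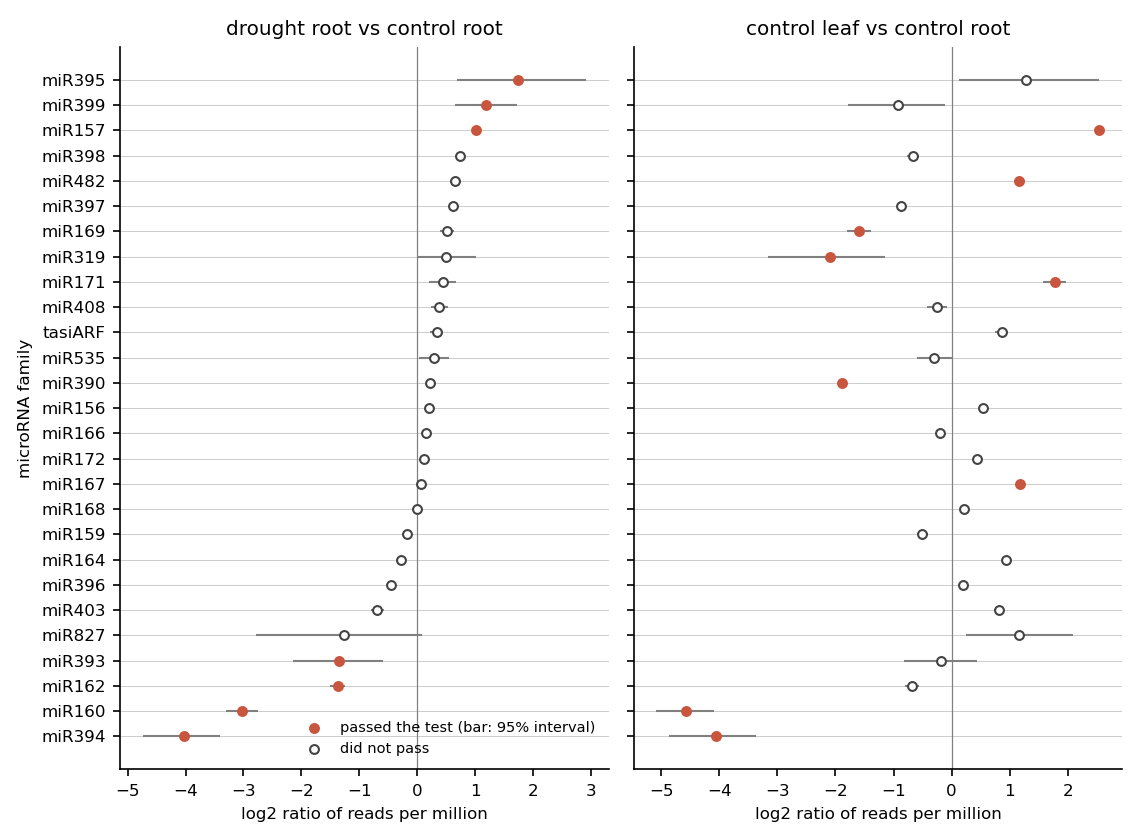
Log2 ratio with 95% counting interval (horizontal axis) of each small RNA family in drought root against control root and in control leaf against control root, filled where it passed the test. In drought root miR394 and miR160 lay lowest at -4.03 and -3.02, and miR395 highest at 1.74.

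Reads of 24 nt, the length of small RNAs that direct DNA methylation, were the largest class in all 4 libraries. They made up 48.5% of reads of 18 to 30 nt in control root, 50.1% in drought root, 57.1% in stem and 52.7% in leaf; reads of 21 nt, the usual length of microRNAs, made up 17%, 16.5%, 12.6% and 18.3%. Reads above 30 nt made up 8.64% of control root, 10.5% of drought root, 0.734% of stem and 5.62% of leaf. The most abundant sequence in control root was that of miR166, at 25751 RPM and 28189 in drought root. A 31 nt sequence matching the start of a histidine tRNA was 6.46-fold lower in drought root (6.38 to 6.54; 11040 against 1709 RPM); all fragments of that start of 30 to 34 nt together were at 0.341 times the control root level (25357 against 8655 RPM). A sequence matching the start of 18S ribosomal RNA was 8.42-fold higher (8.32 to 8.53). Both names rest on textbook sequences and were not checked against a genome or annotation.

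**Figure D4:**
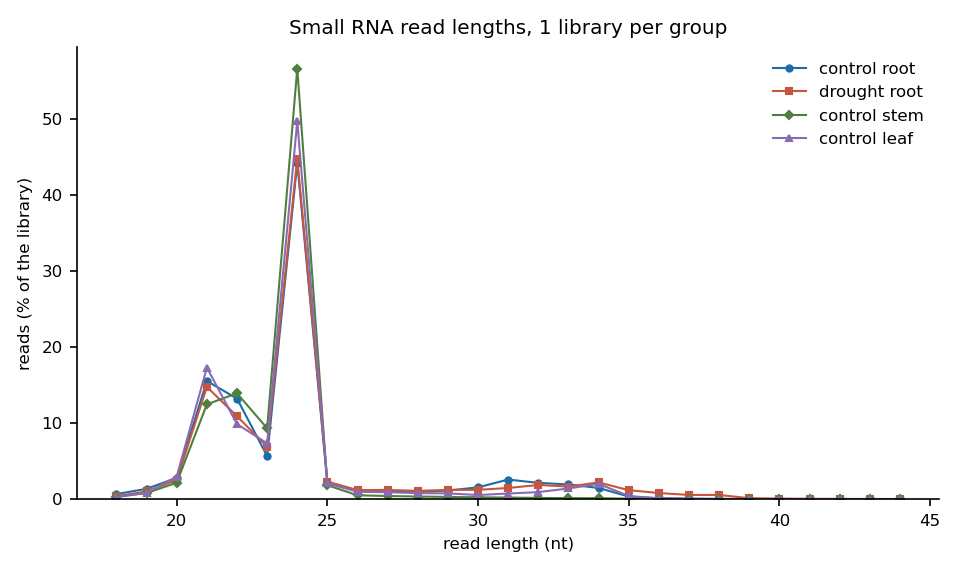
Percent of all reads of each library (vertical axis) by read length in nt (horizontal axis) for control root, drought root, control stem and control leaf. The 24 nt peak was the highest in each, and reads above 30 nt were 10.5% of drought root and 0.734% of stem.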

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

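The tests of the 2 patterns weighed here were all chosen after the results were seen. The thresholds, the lists and the gene tests were chosen before the data were examined.

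Both genes that rose at 6 h and fell at 48 h against the same 0 h library stood out because their direction turned. The ethylene receptor homolog NbS00010982g0109.1 had 26, 82 and 4 counts and was 21.1-fold lower at 48 h than at 6 h (adjusted p 1.05e-18, exact binomial test). The gene NbS00024338g0007.1, described as unknown, had 147, 323 and 52 counts and was 6.38-fold lower. Between the same libraries 5 lists had medians below the central 95% of random lists: class III peroxidases (-0.40), pathogenesis-related proteins (-0.40), jasmonate (-0.98), ethylene (-0.56) and cytosolic ribosomal proteins (-0.22). The ethylene median was above 0 under either other count filter. The cause of these falls was not tested in any of the 5 lists.

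For the 15 pathogenesis-related genes higher at 6 h, shoot tissue in the 6 h sample would have raised the photosynthesis list, but its median log2 ratio was -0.94. Chlorophyll-binding proteins had 84 counts at 0 h and 18 at 6 h, and the whole photosynthesis list had 505 and 450. A single faulty tag did not carry the change in the genes with at least 2 tags of at least 10 copies, since 100% of those tags (16 of 16) moved with their gene; in the other 8 of the 15 genes, which had fewer such tags, a faulty tag and a real change cannot be told apart. Handling of the plants or elapsed time could have raised them without any effect of PEG6000, and with 0 untreated libraries at 6 h or 48 h that explanation and the treatment cannot be told apart. Untreated roots sampled at the same hours would separate them.

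Reads of 35 to 40 nt ending in CCA, the end of a mature tRNA, stood out because lengths above the usual small RNA range had not been part of any question. They came to 8927 RPM in drought root, 23.1-fold above control root (386), where other reads of these lengths were 4.82-fold above. A wider size range in the drought root library would raise both kinds alike: at 36 to 39 nt it did not account for the whole, since the share ending in CCA was at least 1.52 times that of control root at each length, while at 35 and 40 nt the ratio was at most 1.39 and the explanation could hold. General RNA breakdown stayed open: reads from inside the first part of 18S ribosomal RNA, named from textbook sequence alone, were 0.907 times those of control root, but the fragment at its 5' end was 8.42 times as abundant. Whether the drought treatment raised these reads could not be tested with 1 drought root library. An effect of the treatment cannot be told apart from one of the making of that library.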

How the results depend on the processing

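No paired analysis was possible because each group held 1 library. A fold threshold of 4 left 129 higher and 152 lower at 6 h, 251 and 292 at 48 h, and 166 and 136 at 48 h against 6 h, with 34 and 67 shared between 6 h and 48 h. With an assumed biological variation of 0.2 the calls were 60 and 56, 106 and 137, and 39 and 52; with 0.4 they were 1 and 2, 4 and 1, and 0 and 2. The first tag alone gave 226 and 247, 343 and 435, and 190 and 273, and turned the MYB gene NbS00009284g0003.1 at 48 h (0.27). Other scalings kept nearly all named calls. A filter of 50 counts left 3 lists below the central 95% at 6 h, 5 below at 48 h, and 1 above and 2 below at 48 h against 6 h; no filter put 3 above there. Medians changed sign for ethylene genes at 48 h against 6 h (0.14 with either filter), and with 50 counts for gibberellin (-0.13) and photosynthesis (0.25) at 48 h. Families higher in drought root were 1 with TMM, 0 by family share, 1 with no mismatch, 1 with at least 100 reads and 0 with a variation of 0.4, where 0 were lower and 4 differed between organs. miR169 in leaf against root turned to 0.97 with no mismatch. The 24 nt share was 63.6%, 65.0%, 66.6% and 69.8% of distinct sequences in control root, drought root, stem and leaf, 54.5%, 57.9%, 61.9% and 63.6% without the top 100, and 44.3%, 44.8%, 56.7% and 49.8% over 18 to 44 nt. The first tag and the 18 to 44 nt range were added after the results were seen. Not run were pseudocounts for normalized-only values and leaving out annotated rRNA and tRNA reads, since the files carry no annotation.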

Other observations

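Of the tests in this part, the test of suberin and Casparian strip genes was written before its result was seen, and those of the clock genes were chosen after. The genes named in this part were chosen after the values were seen.

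A list of suberin and Casparian strip genes shifted up at 48 h. Suberin and the Casparian strip limit the passive flow of water and solutes across the root. In a list of such genes without those that prompted it, 7 of 29 measured members rose at 48 h, 1 fell, and the median log2 ratio was 1.10. At 6 h 1 of 22 measured members was higher and the median was 0.22. These medians are not over the same genes. Some members passed the filter of 10 counts only through their 48 h counts, and these enter with ratios above 0. An example is the 3-ketoacyl-CoA synthase 1-like gene NbS00003532g0003.1, with 0, 0 and 16 counts. Of the 7 higher members, only NbS00008258g0002.1, with 15 counts, reached 10 counts at 0 h. That model, described as fatty acyl-CoA reductase 3, rose 7.12-fold (4.12 to 13.2). That name alone does not show a role in suberin. Another model of that name, NbS00016139g0007.1 with 12 and 6 counts at 0 h and 48 h, did not pass. An ABCG11-like transporter rose from 0 to 59 counts (at least 20.0-fold) and a model of the CASP-like protein IN26 rose 14.2-fold (4.55 to 71.8); the other IN26 model, with 10 and 24 counts, did not pass. Of 5 measured models of 3-ketoacyl-CoA synthases, which lengthen the fatty acids, 3 rose, that of synthase 10 by 11.7-fold (2.89 to 102). A further CASP-like gene, NbS00037891g0002.1, fell from 15 counts to 0. None of the models named Casparian strip membrane protein 1 was called, and their log2 ratios at 48 h were all below 0 (-2.30, -1.30, -0.51 and -0.30). The hypothesis of a wider rise of suberin genes could have failed in this test. The median lay at percentile 100 of random lists drawn under the same filter. Members with at least 10 counts at 0 h were not tested apart, so a rise among genes already expressed at 0 h is not shown. PEG6000 and 48 h of root growth cannot be separated as the source of the shift.

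Circadian clock genes were called with opposite signs at 6 h, with 3 of 12 measured higher and 4 lower. The 3 higher were all models described as GIGANTEA, and the 4 lower included CONSTANS, which reads day length for flowering. A second GIGANTEA model rose 12-fold at 6 h (5.25 to 33.9) and 21-fold at 48 h (9.39 to 58.4), and an ELF4-like gene fell 2.57-fold (1.60 to 4.24) and 2.35-fold (1.49 to 3.8). At 48 h the evening genes NbPCL1, with 0, 12 and 46 counts, and an APRR5-like gene, with 0, 5 and 28 counts, were also higher. An ELF3-like gene was 7.14-fold higher at 48 h than at 6 h, while the other ELF3-like model, with 39 and 40 counts, was not called. Another ELF4-like model, with 20, 32 and 27 counts at 0 h, 6 h and 48 h, was not called in any comparison.

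The time of day at sampling could produce such a pattern, because these genes swing each day. If 0 h and 48 h fell at the same hour, their levels should have returned by 48 h, but 85.7% (6 of 7) were called the same way at 48 h. The remaining one, the GIGANTEA model NbS00004742g0022.1 with 0, 15 and 8 counts, had too few counts to be tested at 48 h against 0 h. Both comparisons share the 0 h library, which favours calls of the same sign. Over all genes called at 6 h and tested in both, 41.8% of the higher and 56.1% of the lower were called the same way. The explanation that the 0 h library alone stood apart, for example by its sampling hour, would leave 6 h and 48 h alike: 0 of the 4 of these genes that could be tested were called between them, but 4 of 11 measured genes of the whole clock list were higher at 48 h than at 6 h, so it stayed open. Chlorophyll-binding proteins had 84 counts at 0 h against 18 and 20 and moved with the clock genes that fell. The whole photosynthesis list had 505 counts at 0 h against 450 and 416. Shoot tissue in the 0 h sample was not tested as an explanation. A single tag did not carry the change in genes with at least 2 tags of at least 10 copies, as 100% of those tags (9 of 9) moved with their gene, but in 3 of the 7 genes, the At5g37260-like gene among them, there were fewer such tags and that cannot be told apart.

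In reads of 35 to 40 nt that ended in CCA and held the T-arm motif (4258 in control root, 111735 in drought root, 1825 in stem and 5331 in leaf), the base that follows TTCA or TTCG in the T arm of the tRNA was other than A in 85.5% of reads in control root, 82.1% in drought root, 87.6% in stem and 18.5% in leaf. That position is an often methylated adenosine in cytosolic tRNA. The share of counts in the tag listed first was 50.6%, 50% and 46.2% at 0 h, 6 h and 48 h.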
